A study of Candida albicans with 4 samples.

How the data were processed

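The samples were biofilms of Candida albicans SC5314, the strain commonly used as the reference of this yeast, grown at 37 °C for 24 h after adherence. The control group was grown in RPMI-1640 medium (2 libraries) and the amino-acid group in RPMI-1640 with 1.5% amino acids (2 libraries). The labels call the amino acids only AA, and the series title names aspartic acid, cysteine and glutamic acid. The libraries are described as biological replicates in the labels' protocols. Per the labels' protocols, total RNA went into QuantSeq 3′ mRNA-Seq FWD libraries, a kit that primes with oligo(dT) and reads a tag near the 3′ end of a transcript, and these were sequenced as single reads of 101 bp. Such tags need no correction for transcript length, and RNAs that lack a poly(A) tail enter only by priming elsewhere in the molecule.

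The authors deposited 1 table of raw read counts per feature, with 1 column per library and no normalization. FastQC 0.11.5, STAR 2.7.11b and DESeq2 1.44.0 are named in the submitters' processing notes, without saying how each was used. The counting program, genome build, annotation, strand setting and the treatment of reads that match several places are not given in the sources used here. Counts of overlapping or antisense features, and of near-identical copies such as transfer RNA genes, small nucleolar RNA families and the repeated ribosomal DNA, are therefore uncertain. The table held 6461 features. Of these, 6194 were open reading frames named by orf19 number and 267 were other features. Every column belonged to 1 of the 4 samples.

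Before the data were examined, 33 gene lists were fixed by gene symbol (hyphal genes, adhesins, amino acid and sulphur metabolism, stress, metals and others). The reference table of gene names used here (assembly ASM18296v3) contains no orf19 numbers: 0 of the 6194 open reading frames matched it, and 0 of the 639 list genes were found in the count table. The files do not pair orf19 numbers with symbols, so no gene list, no symbol fixed in advance and no chromosome was tested. Checks of GC content or gene length were void for the same reason. By symbol, 134 of the other features matched, of which 126 were transfer RNAs. The rule for named genes was the 10 highest and 10 lowest fold changes among features past the threshold, members of the lists, a set of fixed symbols and, where IDs could not be paired with symbols, at most 2 IDs per direction. No feature passed the threshold. The 4 open reading frames named were therefore chosen after their values were seen, as the 2 per direction with the smallest p among those with an average log2 CPM of at least 5 and no overlap between the groups. In place of the lists, feature classes were read from the names in the table after the files were seen: transfer RNAs, ribosomal RNAs with their spacers, small nucleolar RNAs (snR names), spliceosomal RNAs and features with the CaalfM prefix of the mitochondrial genome. The non-coding RNAs named were also chosen after their values were seen.

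The comparison was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling, filterByExpr at its default minimum count of 10, no covariate, and Benjamini-Hochberg adjustment over the 5360 features that passed the filter. The threshold was an adjusted p of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. Values per library are TMM-scaled CPM, and values of a group are means ± SD (n = 2). Log2 CPM used a prior count of 2. Classes with 3 or more tested members were tested against all other features with camera (limma 3.58.1; preset inter-gene correlation of 0.01), adjusted over the 5 classes. Camera with an estimated correlation was run beside it, and fry, which tests whether the members of a class move on balance and compares them with no other features. Each amino-acid library was also set alone against both controls. Such a fit assumes that the single library varies as the control libraries do.

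Alternatives fixed before the data were examined were DESeq2 (1.42.0), limma-voom, 3 other scalings, no low-count filter, a minimum of 50 reads in 2 libraries, a robust dispersion, the 20 most abundant features left out, the replicate number as a block, and each library left out in turn. A fit on open reading frames alone, the classes and their tests, the thinning of libraries, the fits of single amino-acid libraries and the simulations without change were chosen after the data were seen. The difference between the control libraries was 8.84 times sampling noise (chi-square per degree of freedom over features with 10 reads or more) and that between the amino-acid libraries 147 times, so no library was treated as a copy of another. Intervals of shares are exact 95% binomial intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

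The test was tested on simulated counts for the amino-acid comparison, drawn for the 5360 features with 200 of them changed. With the spread fitted over all 4 libraries, edgeR recovered 0% of 2-fold, 1.49% of 4-fold and 33.3% of 8-fold changes, with 1 false call. With the spread of the control libraries alone, it recovered 71.6%, 89.6% and 95.5%, with 11 false calls. DESeq2 with the spread of all 4 libraries recovered 2.99%, 29.9% and 74.2%, with 30 false calls among 101.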

Results

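RNA of 24 h biofilms was counted in 4 libraries, 2 from the control medium and 2 from medium with 1.5% amino acids. The control libraries held 2833671 and 2829203 counted reads, and the amino-acid libraries 1782571 (replicate 1) and 2325073 (replicate 2). Between 5887 and 6068 of the 6461 features had at least 1 read in a library. Open reading frames took 96.5% and 96.8% of the reads in the controls, 95.1% in amino-acid replicate 1 and 96.9% in replicate 2. The most abundant feature, an open reading frame, held between 4.06% and 5.38% of a library.

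The design asked how transcript levels in biofilms grown under sustained inhibition with amino acids differed from those in untreated biofilms. Counts of small nucleolar RNAs, which guide the modification and processing of ribosomal RNA, were called higher as a class only at the preset correlation. Their median log2 fold change was 1.28 over 37 members (edgeR fold changes, camera adjusted p = 1.3e-07). The class was not called by camera with an estimated correlation (adjusted p = 0.63) or by fry (adjusted p = 0.88). RNAs without poly(A) tails enter these libraries only by priming elsewhere, so such counts need not follow their levels. Without amino-acid replicate 1 the class median was 0.55. With replicate 1 as the only amino-acid library, transfer RNAs (median 2.46), ribosomal RNAs (median 1.15) and the ribonuclease P RNA RPR1 (log2 fold change 3.06) were called higher as well; the 2 class calls were lost with an estimated correlation in that fit (adjusted p = 0.31 for each). Among open reading frames, 4 were picked for a small p and no overlap between the groups. Of these, orf19.2989 and orf19.1598 lay above both controls (log2 fold changes 2.55 and 2.69), and orf19.2133 and orf19.2897 below (-3.64 and -3.23). Groups did not overlap in 38.0% of all features, and in a mean of 40.8% in simulations with no change. None of the 4 open reading frames passed edgeR's test over all features. The amino-acid libraries also differed more from each other than the controls did.

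No single feature differed between the groups at an adjusted p of 0.05 with edgeR's quasi-likelihood test: 0 of 5360 tested features were higher and 0 were lower, with a smallest adjusted p of 0.779. An unadjusted p under 0.05 was reached by 324 features, where 268 are expected by chance. Of these, 168 were higher and 156 lower with amino acids. Limma-voom also called 0 features, with 302 at an unadjusted p under 0.05. DESeq2 tested 6282 features and left 1096 of them without an adjusted p, so these could not be called. It called 46 (25 higher, 21 lower), with 367 at an unadjusted p under 0.05, where 314 are expected by chance. These 46 were 40 open reading frames, 5 small nucleolar RNAs and 1 transfer RNA. With either amino-acid library left out, edgeR called many features in both directions. Those fits take their spread from the controls alone. The biological coefficient of variation was 12.9% for the controls and 64.3% for the amino-acid libraries. Their calls therefore tell how 1 library differs from the controls, not what amino acids change.

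The 4 open reading frames had an edgeR adjusted p of 0.779 each. The files do not pair their numbers with gene names. Counts of orf19.2989 gave 34.5 ± 6.21 CPM in the controls and 202 ± 41.2 CPM with amino acids (SD, n = 2), a log2 fold change of 2.55 ± 0.41 (SE). For orf19.1598 the levels were 10.5 ± 1.11 and 67.8 ± 20.8 CPM, a log2 fold change of 2.69 ± 0.44. In the other direction, orf19.2133 stood at 78.5 ± 2.58 CPM in the controls and 6.13 ± 1.93 CPM with amino acids, a log2 fold change of -3.64 ± 0.44. The levels of orf19.2897 were 72.7 ± 18.0 and 7.80 ± 1.48 CPM, a log2 fold change of -3.23 ± 0.45. DESeq2 called all 4, with adjusted p of 0.0084 for orf19.2989, 0.017 for orf19.1598, 0.00033 for orf19.2133 and 0.0028 for orf19.2897. Over all tested features, 976 had both amino-acid libraries above both controls and 1062 had both below. Together these were 38.0% of the features. Chance gives 33.3% for 2 libraries against 2 of equal spread. Simulated libraries with no change and the unequal spread of these groups gave a mean of 40.8% (39.7% to 42.2% in 20 simulations). The observed share lay above the first value and below all simulated ones, whose spread was fitted to only 2 libraries per group. It therefore gives no evidence of a change. A permutation test of a single feature cannot go below a two-sided p of 0.33 in this design.

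The amino-acid libraries differed from each other far more than the controls did. The log2 difference between the controls had an SD of 0.39 over the 5360 features, and 3.02% of features differed by more than 2-fold. Between the amino-acid libraries the SD was 1.46 and 47.3% of features differed by more than 2-fold. Replicate 2 differed from the controls by an SD of 0.85 and 0.81, and replicate 1 by 1.25 and 1.34. The biological coefficient of variation fitted to each group alone was 12.9% for the controls and 64.3% for the amino-acid libraries.

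**Figure D1:**
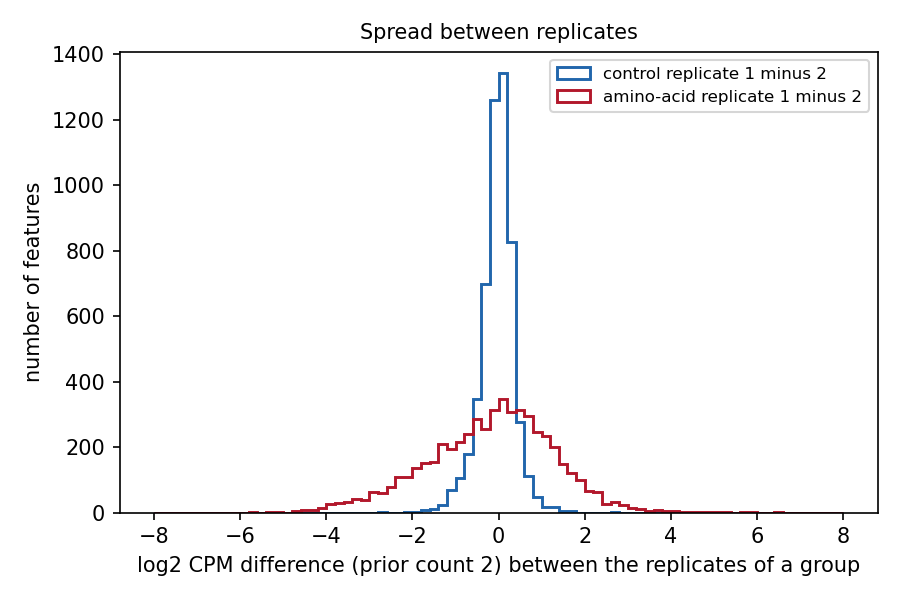
Histogram of the log2 CPM difference (prior count 2) between the replicates of each group, with the number of features on the vertical axis; blue is control replicate 1 minus 2 and red is amino-acid replicate 1 minus 2. The red distribution is the wider one, with an SD of 1.46 against 0.39.

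The calls of the single amino-acid libraries, each set against both controls, were then compared. Each such fit takes its spread from the controls, so its calls describe 1 library and not the amino-acid group. Of the 5418 features tested in both fits, 155 were higher in both libraries and 277 lower in both, while 480 were called in opposite directions. Independent lists of these sizes would share 179 higher, 197 lower and 375 opposite. Simulated libraries with no change, set against simulated controls shared by both fits, had 0 of each kind in common. They gave a mean of only 0.15 and 0.45 calls in all. This 0 therefore does not measure what the shared controls add to the overlap. The features called the same way in both were 150 open reading frames and 5 small nucleolar RNAs among those higher, and 276 open reading frames and 1 spliceosomal RNA among those lower. Fold changes of the libraries against the shared controls correlated across features by 0.10, and features are not independent replicates. Simulated libraries with no effect gave 0.29, but all of them were drawn with the spread of the controls. The biological coefficient of variation was 12.9% for the controls and 64.3% for the amino-acid libraries. With less spread of their own, simulated libraries share more through the controls, so 0.29 is no baseline for 0.10. The covariance was 0.130 observed and 0.042 simulated. Against separate controls, the correlation was 0.11 with libraries matched by replicate number and -0.03 with numbers crossed. Part of any overlap may come from the shared controls, since splitting them would leave only 1 library on each side.

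**Figure D2:**
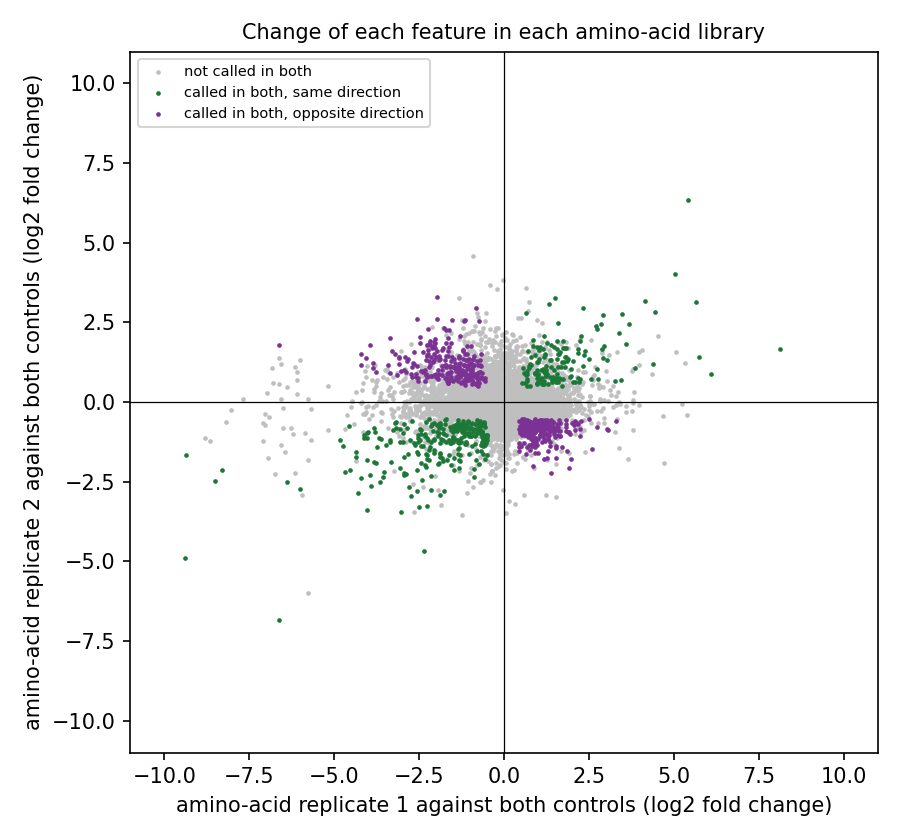
Log2 fold change of amino-acid replicate 1 (horizontal) and replicate 2 (vertical), each against both controls, for the 5418 features tested in both fits; green points were called in both fits in the same direction and purple points in opposite directions. The 432 green points are fewer than the 480 purple ones.

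Of the 37 small nucleolar RNAs tested, 32 had a positive log2 fold change. The call of the class against other features was lost with an estimated correlation (adjusted p = 0.63). Fry, which tests whether the members move on balance and makes no comparison with other features, gave an adjusted p of 0.88. No single member passed edgeR's test over all features or adjusted over the list alone; 9 were higher and 0 lower at an unadjusted p under 0.05. In 23 of the 37 both amino-acid libraries lay above both controls, and in 2 both lay below, where either happened in 40.8% of all features in the simulations without change. The class median was 1.65 in replicate 1 alone and 0.55 in replicate 2 alone. Camera called the class in both of these fits at the preset correlation and in neither with an estimated one. The estimates were -0.02 and 0.007, below the preset 0.01, so correlated members do not account for that loss. Each of these fits had 1 residual degree of freedom. Replicate 1 alone had 23 members called higher and 5 lower, and replicate 2 alone had 10 higher and 1 lower. Calls went in opposite directions for snR5a (log2 fold change -3.87 in replicate 1 alone and 1.08 in replicate 2 alone), snR10c (-0.66 and 1.51) and snR42a (0.85 and -1.06).

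The 5 members called higher in each library alone were snR71, snR75, snR13, snR128 and snR73. The level of snR71 was 6.59 and 5.47 CPM in the controls, 310 CPM in amino-acid replicate 1 and 54.0 CPM in replicate 2, a log2 fold change of 4.90 ± 1.00 (SE). For snR75 the controls held 10.1 and 16.4 CPM, replicate 1 held 3757 CPM and replicate 2 held 42.4 CPM. For snR13 these values were 31.6, 42.4, 2535 and 68.6 CPM, and for snR128 they were 21.2, 19.5, 103 and 44.6 CPM. DESeq2 called snR71 (adjusted p = 8.8e-06), snR75 (adjusted p = 5.3e-07) and snR13 (adjusted p = 0.00029), and gave snR128 an adjusted p of 0.31. The most abundant member, snR33a, went the other way in replicate 1, with 802 CPM there against 5059 and 5751 CPM in the controls and 4798 CPM in replicate 2. Its log2 fold change was -2.76 with replicate 1 alone, and it was not called with both libraries (edgeR adjusted p = 0.86). All small nucleolar RNAs together took 0.649% and 0.749% of reads in the controls, 0.869% in replicate 1 and 0.769% in replicate 2.

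Transfer RNAs were also called higher as a class at the preset correlation, but only amino-acid replicate 1 showed a rise. Of 32 tested, 29 had a positive log2 fold change, with a median of 1.35 (camera adjusted p = 0.00042; adjusted p = 0.84 with an estimated correlation). With limma-voom the class was not called (median 0.60, adjusted p = 0.086). Their share of reads was 0.165% in amino-acid replicate 1 (exact 95% interval 0.159% to 0.171%). It was 0.0258% in replicate 2 (0.0237% to 0.0279%) and 0.0267% and 0.0314% in the controls. Without replicate 1 the class median was -0.44 (adjusted p = 0.16), and 0 members were called higher. The gene tN(GUU)3, for an asparagine transfer RNA, stood at 171 CPM in replicate 1, 4.87 CPM in replicate 2 and 6.59 and 6.49 CPM in the controls. DESeq2 nevertheless called it higher (adjusted p = 0.049).

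Other structured RNAs of replicate 1 also stood apart. RPR1, the RNA of ribonuclease P, gave 11643 CPM in replicate 1 and 760 CPM in replicate 2, against 1391 and 1394 CPM in the controls. Neither direction was called over both libraries (edgeR adjusted p = 0.82). The log2 fold change was 3.06 with replicate 1 alone and -0.89 with replicate 2 alone. SCR1, the RNA of the signal recognition particle, gave 1712 and 517 CPM in the amino-acid libraries and 446 and 365 CPM in the controls, and was called higher with replicate 1 alone only. The U1 spliceosomal RNA (SNRNAU1) was below both controls in both, at 592 and 253 CPM against 762 and 970 CPM, a log2 fold change of -1.04 ± 0.61 (SE, edgeR adjusted p = 0.82). It was the only spliceosomal RNA called lower in each library alone.

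The ribosomal RNA class did not pass the test (6 members, median 0.60, camera adjusted p = 0.20), nor did the spliceosomal RNAs (5 members, median 0.35, adjusted p = 0.97) or the mitochondrial features (5 members, median 0.24, adjusted p = 0.78). At the preset correlation the ribosomal class was called higher without amino-acid replicate 2 (median 1.15) and without control replicate 2 (median 0.82). Its median was -0.36 without amino-acid replicate 1. With an estimated correlation both calls were lost, in fits with 1 residual degree of freedom. That estimate was -0.07 without amino-acid replicate 2 and 1 without control replicate 2. The first loss therefore does not show correlated members. The spliceosomal median was -0.79 without amino-acid replicate 1, and the mitochondrial median was -0.24 without amino-acid replicate 2 and 1.34 without replicate 1. RDN25, the large ribosomal RNA, gave 21867 and 17518 CPM in the controls and 29057 and 16431 CPM with amino acids. RDN18, the small ribosomal RNA, gave 2400 and 2129 CPM against 3128 and 1704 CPM. Ribosomal RNA and its spacers made up 2.48% and 2.05% of reads in the controls, 2.71% in amino-acid replicate 1 and 2.09% in replicate 2. Mitochondrial features took 0.0218% and 0.0222% in the controls and 0.0157% and 0.0259% with amino acids.

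**Figure D3:**
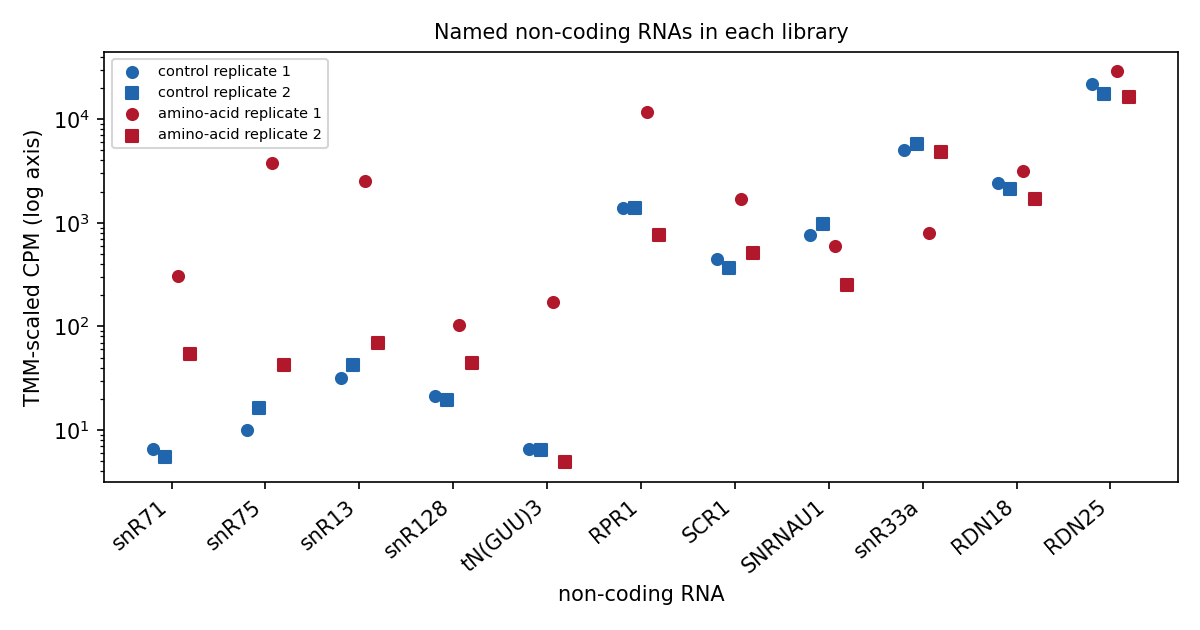
TMM-scaled CPM (log axis) of 11 named non-coding RNAs in each of the 4 libraries; blue is control, red is amino acids, circles are replicate 1 and squares are replicate 2. The red circles of snR75, snR13, tN(GUU)3 and RPR1 lie far above the other points, and both red points of snR71 and snR128 lie above the blue ones.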

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

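The fit on open reading frames alone, the estimated correlation and fry were chosen after the data were seen. The count of 0 features was the same with limma-voom, the 3 other scalings, both other filters and a robust dispersion. It was also the same with the 20 most abundant features left out and with open reading frames alone. In these fits 242 to 352 features had an unadjusted p under 0.05. Without either control library the count was 0 too. Those fits take their spread from the amino-acid libraries alone, which differ widely, so that 0 is no support. DESeq2 called 25 higher and 21 lower, all by 2-fold or more. The fit with the replicate number as a block (1 residual degree of freedom) called 14 higher and 22 lower, all by 2-fold or more, among them snR71 (edgeR adjusted p = 5.2e-06) and the 4 named open reading frames (adjusted p from 0.00026 to 0.021). Deviations of same-numbered libraries from their group means correlated by 0.25. With 2 pairs and no stated shared day, whether the numbers pair the samples cannot be told. Leaving out each library in turn, features higher ranged from 0 to 1381 and lower from 0 to 1357; by 2-fold or more, higher ranged from 0 to 860 and lower from 0 to 1058. The high ends came without amino-acid replicate 2 (1381 and 1357) and the counts without replicate 1 were 745 and 785; in both, the lone amino-acid library is assumed to vary as the controls do. The number of classes called was 2, but 1 with limma-voom and with 50 reads in 2 libraries (which left too few transfer RNAs to test), 0 with an estimated correlation, and 1 to 3 with a library left out (0 in each of these with an estimated correlation). Fits with a library left out have 1 residual degree of freedom, so losing calls there does not by itself show correlated members. Fry, which tests for a change on balance and not against other features, called 0 classes in the main fit. The small nucleolar RNA median of 1.28 and the transfer RNA median of 1.35 lost their calls with an estimated correlation, and limma-voom gave transfer RNAs a median of 0.60 with no call. With a library left out, class medians ranged from -0.44 to 2.46 for transfer RNAs, -0.36 to 1.15 for ribosomal RNAs (called without amino-acid replicate 2 and without control replicate 2), -0.79 to 0.90 for spliceosomal RNAs and -0.24 to 1.34 for mitochondrial features, each going below 0 by the loss of 1 amino-acid library; small nucleolar RNAs stayed between 0.55 and 1.65. Fold changes that changed sign without amino-acid replicate 1 were those of RPR1 (range -0.89 to 3.06), RDN25 (-0.28 to 0.55), RDN18 (-0.42 to 0.46) and tN(GUU)3 (-0.44 to 4.69). RDN18 also turned to -0.0201 with upper-quartile scaling and -0.0335 with library size only. RPR1, RDN25, RDN18 and tN(GUU)3 lay below both controls in amino-acid replicate 2, on which a fit without replicate 1 rests. Why the amino-acid libraries differ was not tested. The median log2 fold change of all tested features lay between -0.005 (replicate block) and 0.149 (DESeq2) over the settings that kept all 4 libraries. The gene lists and chromosomes fixed in advance, and the alternative without ALS, SAP and HGT members, were not run for want of gene symbols. Depth limits low features: 3 reads correspond to 1.06 CPM in a control and 1.68 CPM in amino-acid replicate 1.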

Other observations

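The tests of a mislabelled control, of one response reached to different extents and of a general rise of non-coding RNA were chosen only after the results they bear on were seen. Further small nucleolar RNAs lay above both controls in both amino-acid libraries, without passing edgeR's test over all features. For snR77b the controls held 7.29 and 6.84 CPM, amino-acid replicate 1 held 287 CPM and replicate 2 held 16.9 CPM, and DESeq2 called it higher. For snR47 these values were 4.16, 2.05, 9.53 and 11.6 CPM, and for snR73 they were 182, 213, 491 and 292 CPM. Of 89 non-coding features tested, 10 had an unadjusted p under 0.05, all of them higher with amino acids: 9 small nucleolar RNAs and the valine transfer RNA gene tV(UAC)1. The U6 spliceosomal RNA (SNRNAU6) was called in opposite directions in the single libraries, at 252 CPM in replicate 1 and 74.6 CPM in replicate 2 against 120 and 136 CPM in the controls. All these features were chosen after their values were seen.

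The wide spread between the amino-acid libraries (SD of the log2 difference 1.46, against 0.39 for the controls) was set against 3 explanations. Lower depth of replicate 1 is argued against: with every library thinned to 1782571 reads, the controls differed by an SD of 0.43 and the amino-acid libraries by 1.4. A mislabelled control is argued against as well, since the smallest SD between an amino-acid library and a control was 0.81. A single response reached to different extents would make the changes correlate when each library is set against a different control, and the larger of the 2 correlations was 0.11. A difference in the cultures or their treatment, in RNA handling or in library preparation, and a sample exchanged with one from outside these groups, stay open and were not tested, as does a response to amino acids that itself varies between cultures.

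The higher small nucleolar RNA class may have different origins in the libraries. In amino-acid replicate 1 the tRNA, ribosomal and spliceosomal classes had positive medians too (the last not called), and the median of these 3 class medians was 1.15, which is consistent with a rise of many RNAs without poly(A) tails in that library. The rise did not cover all of them: with replicate 1 alone, 5 small nucleolar RNAs were called lower (among them snR33a at -2.76 and snR17A at -2.66 on the log2 scale), U1 was called lower (-0.56) and the mitochondrial median was -0.24. In replicate 2 the same median was -0.44, so such a rise is argued against there, while small nucleolar RNAs still had a median of 0.55. A response of small nucleolar RNAs to amino acids is a hypothesis that stays open. The members called higher in each library alone are no support for it. They are no more than independent lists of the same sizes would share, and both fits used the same controls. For snR5a and snR10c the fold changes went in opposite directions, down in replicate 1 and up in replicate 2.

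DESeq2 called 46 of 6282 features, of which 1096 had no adjusted p. Of the 46 calls, 44 were among the 5360 features in which edgeR called 0. In 20 simulated data sets, these 5360 features were drawn with no change and the spread of each group. DESeq2 made a mean of 3.55 calls there (0 to 11) and edgeR 0. In the simulated counts with 200 features changed and the spread of all 4 libraries, 30 of 101 DESeq2 calls were false. False calls could therefore account for part of the 44. How many is open. A bound (under 0.1 times the real number of calls) was set before these simulations were run, but after the data were seen, and was met. It rests on simulated libraries whose spread was itself fitted to 2 libraries per group, and so excludes nothing.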
